A study of Mus musculus with 401 samples.

How the data were processed

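Single nuclei of mouse dentate granule neurons were sorted with antibodies against PROX1 and CTIP2, the product of Bcl11b, after the animals had explored an unfamiliar environment for 1 h. Nuclei were collected at 1 h or at 4 h. Per the labels, immature neurons were about 5 weeks old and carried a nuclear GFP (Sun1-sfGFP) switched on by a tamoxifen-dependent Cre, with tamoxifen given at 200 mg/kg on 7 days, and all other granule nuclei were called mature. Active nuclei held detectable ARC protein at the sort and inactive nuclei did not. Each library was 1 nucleus amplified by a plate-based full-length method in 384-well plates and read with 50-bp single-end reads. The 401 nuclei came from 14 mice, 5 at 1 h and 9 at 4 h, and every column of the tables was assigned to its nucleus.

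The authors deposited expected counts per gene and nucleus. Per the submitters' processing notes, RSEM and Bowtie were used with the mm10 (GRCm38) build; their versions and the gene annotation are not given in the sources used here. Of the count cells, 9% were not whole (tolerance 1e-09). The second deposited table is named for TPM but holds log2(TPM + 1) values: the highest was 19.2, and transforming back gave between 986133 and 1000000 TPM per nucleus over distinct features. Both tables list 46615 features, of which 30294 had a count in any nucleus. Genes that shared 1 estimate repeated the same values, so 6306 listed entries were merged into 1945 shared features, which left 25933 distinct features; the share of reads of each gene within a merged feature is uncertain. Symbols are given as in the tables, some of them older ones (Lphn3, Sfrs2, Mfsd4, Dbc1). Of 21737 entries named by an Ensembl ID, 20990 had a symbol in the GENCODE vM21 gene names, which also gave the GRCm38 positions printed for a few genes.

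The replicate was the mouse. Expected counts were summed over the nuclei of 1 mouse and 1 state where there were at least 3 nuclei, then rounded to whole numbers, which gave 49 sums in 8 groups (5 per group at 1 h; at 4 h, 5 for immature active nuclei and 8 for each of the other states). Genes were kept by edgeR's filterByExpr with the 8 groups (minimum count 10, minimum total count 15) and a count in at least 20 nuclei, which left 12918. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, robust dispersions, all 8 groups in 1 fit and the mouse as a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The block is used because the states of 1 number come from the same animal. Deviations from the group means had a median correlation of 0.0797 between states of the same mouse (range -0.012 to 0.553; 28 of 65 pairs over 0.1) and of -0.0101 between states of different mice of the same time.

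Limma (3.58.1, with an intensity trend and robust variances) on the mean log2(TPM + 1) per mouse and state, in which each nucleus has the same weight, was planned as an alternative. It is printed beside edgeR because edgeR called few genes, a decision made after those counts were seen. Its differences are on the log2(TPM + 1) scale, which understates the change of genes at low level. Where all nuclei of a group were near 0, levels and limma differences are given in place of edgeR's fitted fold changes. Standard errors (SE) are those of the fit, and SDs are over mice. The median difference of all tested genes was -0.11 in mature nuclei at 1 h and within 0.08 of 0 in the other comparisons with limma; with edgeR it was -0.39 for activity in immature nuclei at 1 h, -0.37 and -0.28 for the difference of the activity change between ages at 1 h and 4 h, and within 0.19 of 0 in the other comparisons.

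The comparisons, gene lists and rule for named genes were fixed before the data were examined. There were 11 comparisons: active against inactive nuclei in each age at each time, the difference of those changes between ages and between times, and immature against mature nuclei that were inactive or active. The rule named up to 10 higher and 10 lower genes with the smallest p among those past the threshold that had a count in at least 25% of the nuclei of a group and the fitted sign in at least 80% of the mice, without clone-numbered genes; where fewer than 3 genes passed, 3 with the smallest p were named as not passing. Up to 4 passing members were named per list, otherwise up to 2, and Arc, Fos, Prox1 and Bcl11b are given in any case. For limma the same rule was applied, also after the counts were seen.

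Gene lists were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over 209 pairs of 19 lists and 11 comparisons. The lists were rapid response, delayed response, MAP kinase feedback, secreted and synaptic plasticity, transcription and chromatin regulators of activity, immature neuron, mature granule cell, granule cell identity, glutamate receptors, GABA receptors, potassium channels, axon guidance, heat shock, neural stem and progenitor, astrocyte, oligodendrocyte lineage, microglia, GABAergic interneuron, and CA pyramidal and mossy cell. Some genes are in several lists, and Arc was left out of the response lists because its protein defined the sort. The mitochondrially encoded list and the endothelial and mural list had fewer than 3 members past the filter and were not tested.

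Rapid and delayed response scores were the mean log2(CPM + 1) over 17 and 32 genes per nucleus, averaged per mouse and state, and were compared with two-sided exact sign-flip permutation tests over mice. Genes detected were counted after thinning each nucleus to 93752 counts, which left out 40 nuclei. In a held-out comparison, genes that rose with activity in mature nuclei were chosen without 1 mouse and their change was measured in that mouse. Alternatives were other size factors, filters and tools (DESeq2 1.42.0), no block, other minimum numbers of nuclei, only the groups compared, leaving out nuclei with few genes, leaving out mice 134, 135 and 138 or each mouse in turn, other pseudocounts and weights, and leaving out nuclei of near-identical pairs of libraries; the closing section gives their effect. Pairs were called near-identical when log2 counts correlated over 0.7. Computations on scores used Python with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures used matplotlib 3.10.9.

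The tests were tried on simulated nuclei drawn from each gene's real mean and spread over nuclei and the real totals, with 200 genes raised in mature active nuclei. Nuclei and genes were drawn independently, without differences between mice or batches. The raised genes were taken from those with higher counts, and limma was run on log2(CPM + 1). DESeq2 took its size factors from positive counts here and by its default method in the real data. The shares recovered and the unchanged genes called therefore need not hold for the real mice. For mature nuclei at 1 h, with 12918 genes tested, edgeR recovered 1.43%, 8.57% and 25% of genes raised 4-, 16- and 64-fold and limma 0%, 15.7% and 30%, each with 0 unchanged genes called, while DESeq2 called 188 unchanged genes. For mature nuclei at 4 h with the same number of genes, edgeR recovered 0%, 17.1% and 41.7% with 2 unchanged genes called, limma 2.86%, 21.4% and 48.3% with 4, and DESeq2 called 919 unchanged genes. In the test of the difference between ages, with the same number of genes, limma recovered 0%, 2.86% and 10% at 1 h and 0%, 10% and 23.3% at 4 h, and edgeR 0%, 2.86% and 11.7% and 0%, 7.14% and 13.3%, with 8 unchanged genes called by limma at 4 h and 0 in the other 3. This library method adds no molecular identifiers, so reads are not independent molecules, and counts say nothing of PCR copies.

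Whether counting used the strand is not given in the sources used here, so values of named genes that overlap another gene in the annotation are uncertain. Among these are Myef2 with Slc24a5, Schip1 with Iqschfp, Nrn1 with Fars2, Sfrs2 with Mettl23, Gas7 with Glp2r, Ano3 with Muc15, Per3 with Camta1, Twf1 with Irak4 and Kif17 with Sh2d5, and genes with a noncoding or antisense partner such as Inhba, Bdnf, Kdm6b, Dock3, Lphn3 and Jun.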

Results

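RNA was measured in 401 single nuclei of dentate granule neurons from 14 mice that had explored an unfamiliar environment for 1 h. The labels define 4 states, mature or immature and active or inactive, each collected at 1 h (5 mice) or 4 h (9 mice). At 1 h there were 61 mature active, 44 mature inactive, 42 immature active and 63 immature inactive nuclei. At 4 h these numbers were 54, 44, 32 and 61. The total count per nucleus ranged from 7538 to 3145009 with a median of 660782, and the number of genes detected from 1746 to 6754 with a median of 4811. Malat1, an abundant nuclear long noncoding RNA, took 12.3% of all counts. By group medians, nuclei at 4 h were deeper in genes than those at 1 h. Median genes detected ranged from 3427 to 4470 in the groups at 1 h and from 5254 to 5658 in those at 4 h. In nuclei thinned to 93752 counts, the mice at 1 h differed. Means per state were 1367 to 1800 in mouse 62 and 1868.5 to 2553 in mouse 60. These mice gave 30 and 70 of the 210 nuclei at 1 h. Mice 66, 69 and 70 had 3086 to 3297, 3609 to 3817 and 3687.5 to 3854. Their values lay within the range of 2367 to 4291 at 4 h. Each library name prefix held mice of 1 time only, so time and library batch cannot be told apart. Values are means over mice unless stated otherwise. P-values of genes rest on the spread of state differences between mice, estimated from all 8 groups. Those of exact tests rest on values per mouse. Those of camera compare the genes of a list with all other genes. Counts of genes at an unadjusted p under 0.05 are out of 12918 tested. Chance alone would give a share of about 0.05 of these, and several of the counts lie near or under that share.

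Arc, whose protein was the activity marker of the sort, followed the labels. Its mean level in log2(TPM + 1) was 5.49 ± 2.1 (SD, n = 5 mice) in mature active nuclei at 1 h against 0.53 ± 0.65 in mature inactive ones, and 7.9 ± 1.61 against 0.34 ± 0.4 at 4 h (n = 8). Arc in immature active nuclei was 2.94 ± 2.51 at 1 h (n = 5) and 4.69 ± 3.56 at 4 h (n = 5), with inactive nuclei at 0.25 ± 0.29 and 0.44 ± 0.48. A count of Arc was found in 77% and 90.7% of mature active nuclei at 1 h and 4 h and in 59.5% and 68.8% of immature active ones, against 11.4% to 29.5% in the inactive groups. Prox1 and Bcl11b, whose proteins were the other sort antigens, did not pass the threshold in any comparison with edgeR or limma. Some sex genes followed the labels, with an exception. Xist reached 100 CPM in 59.4% of the nuclei from 5 females and in 1 nucleus from 9 males. Ddx3y and Eif2s3y together reached it in 59.3% of male nuclei and in 0 female ones. The Y-linked genes Kdm5d and Uty did not part the sexes, with a count in 86.5% and 61.2% of female nuclei and in 92.6% and 74.5% of male ones. The limit and the pair Ddx3y and Eif2s3y were chosen after the values were seen. The male exception is a mature active nucleus at 4 h of mouse 106 whose counts correlated at 0.952 with a mature inactive nucleus of the female mouse 121. Of 80200 pairs of nuclei, 4 correlated over 0.7 (median 0.272). The other 3 pairs each came from 1 mouse, and 2 of those joined nuclei of different states.

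The first comparison asks which transcripts mature granule neurons carry when they are active at 1 h. Active nuclei held more RNA of activity-regulated genes. Inhba, the activin A subunit, rose by 6.27 ± 1.07 on the log2(TPM + 1) scale (limma difference ± SE; limma adjusted p = 0.00122, edgeR adjusted p = 0.00106), from 0.01 ± 0.02 (SD, n = 5) to 6.28 ± 3.1. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, rose by 4.77 ± 0.73 on the log2 scale of summed counts (edgeR adjusted p = 0.00127). Schip1, a protein of the axon initial segment, rose by 2.5 ± 0.4 (edgeR adjusted p = 0.00196). These 3 genes were higher in 5 of 5 mice. With limma, Homer1, a scaffold of the postsynaptic density, rose by 5.37 ± 0.66 (adjusted p = 7.93e-06) and Sik1, a salt-inducible kinase, by 3.65 ± 0.53 (adjusted p = 0.00013), each in 5 of 5 mice. Kdm6b, a histone H3 lysine demethylase, rose by 4.93 ± 0.79 (limma adjusted p = 0.000574) in 5 of 5 mice. Further limma increases in 5 of 5 mice were those of Plk2 (6.31), Bc049807 (4.27), Pim1 (3.92), Gadd45b (3.06) and Midn (2.22), with adjusted p from 0.00013 to 0.00146. With limma 60 genes were higher and 10 lower, and at an unadjusted p under 0.05 there were 423 higher and 598 lower. Pdcd4, an inhibitor of translation initiation, fell by 5.84 ± 0.71 (limma adjusted p = 7.93e-06), from 7.87 ± 1.41 to 2.02 ± 1.22. The transcription factor Tcf4 fell by 3.44 ± 0.65 (limma adjusted p = 0.00404), each in 5 of 5 mice. Myef2 (-4.53) and Slc24a5 (-4.78), which overlap on opposite strands, Dpf1 (-2.99), Lin7b (-3.52) and Zfp187 (-3.01) were lower in 5 of 5 mice and Abcc5 (-3.18) in 4 of 5, with limma adjusted p up to 0.0463.

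In this comparison the rapid response list, immediate early genes without Arc, rose as a group with all 17 measured members positive (median limma difference 1.48; camera adjusted p = 7.31e-12). Of its members 0 passed with edgeR (8 adjusted over the list alone) and 6 with limma (12 adjusted over the list alone), among them Fosb (1.38, 4 of 5 mice), Fbxo33 (2.32), Atf3 (2.02) and Nr4a1 (2.9). Fos itself did not pass, at 2.29 ± 1.31 (SD, n = 5) in active and 0.52 ± 0.72 in inactive nuclei (limma adjusted p = 0.12). The delayed response list had 31 of 32 members positive (median 1.74; camera adjusted p = 2.1e-24), with 2 members passing in edgeR (14 adjusted over the list alone) and 10 in limma (21 adjusted over the list alone). The list of secreted and synaptic plasticity genes, which shares Homer1, Inhba, Bdnf and others with it, had 20 of 25 positive (median 0.62; camera adjusted p = 9.54e-08), 1 member passing in edgeR and 6 in limma (5, and 9 higher with 1 lower, adjusted over the list alone). Its members Bdnf, a neurotrophin, and Nrn1, neuritin, rose by 4.54 ± 0.85 (limma adjusted p = 0.00383) and 4.69 ± 0.99 (limma adjusted p = 0.0114) in 5 of 5 mice. MAP kinase feedback genes had 9 of 14 positive (median 0.38; camera adjusted p = 0.0011), with Spry2 alone passing in each tool (1 in edgeR and 3 in limma adjusted over the list alone). Transcription and chromatin regulators had 19 of 28 positive (median 0.26; camera adjusted p = 0.00387), with 2 passing in limma (1 in edgeR and 4 in limma adjusted over the list alone), Kdm6b and the methylcytosine dioxygenase Tet3 (3.52 ± 0.8). Heat shock genes had 9 of 13 positive (median 1.17; camera adjusted p = 0.0268, and adjusted p = 0.0544 with an estimated correlation), with 0 members passing in either tool (2 in edgeR and 1 in limma adjusted over the list alone). In all, edgeR called 3 genes, all higher (949 at an unadjusted p under 0.05), and limma 70, 60 higher and 10 lower (1021 unadjusted), with 3 called by both. Without the mouse block edgeR called 1 and limma 44. The limma count was 19 without mouse 60, 42 without mouse 66, 38 without mouse 69 and 45 without mouse 70. Spry2 and Schip1 were lost without the block (edgeR adjusted p = 0.338 for Spry2).

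**Figure D1:**
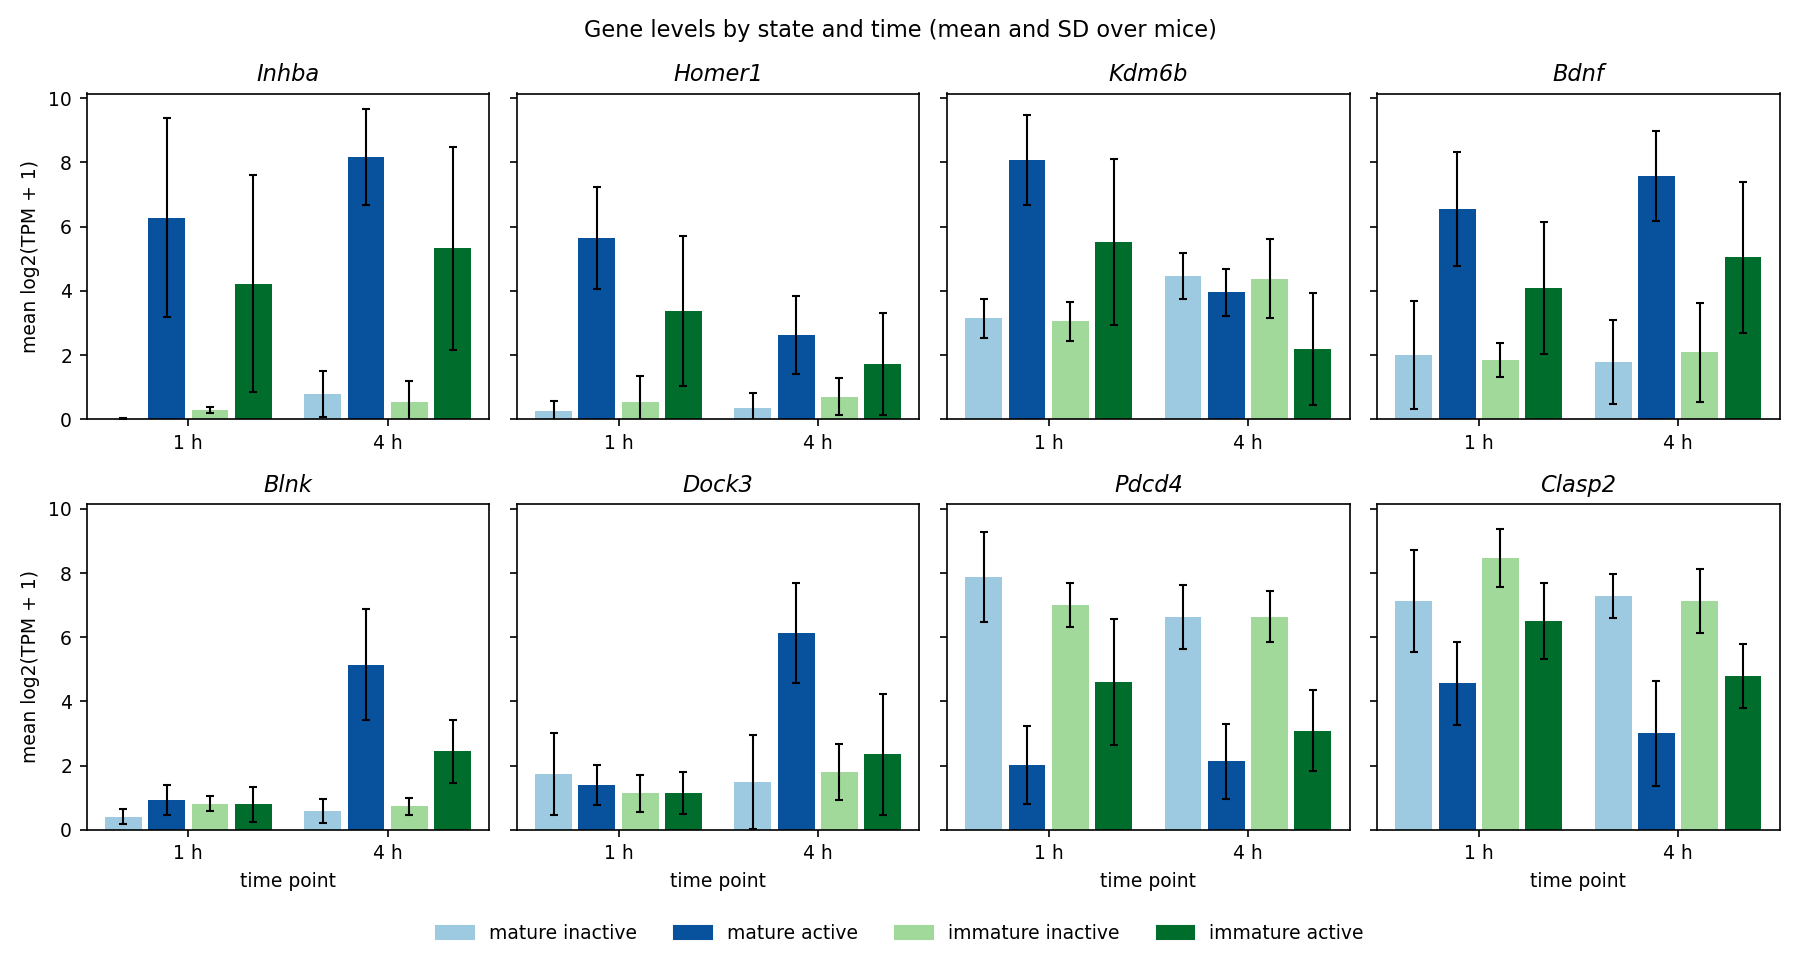
Bars give the mean level in log2(TPM + 1) over mice, with the SD as error bar, of 8 genes in mature and immature, active and inactive nuclei at 1 h and 4 h (n = 5 mice per group at 1 h; at 4 h 5 for immature active nuclei and 8 for the others). Inhba lay at 6.28 and 8.17 in mature active nuclei at 1 h and 4 h and at 0.01 and 0.78 in mature inactive ones, and Pdcd4 at 2.02 and 2.14 against 7.87 and 6.64.

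At 4 h the same question gave the largest set of changed genes. Mature active nuclei held more Inhba (limma difference 7.39 ± 0.87, adjusted p = 6.14e-07; edgeR adjusted p = 0.000198). They held more Blnk, an adaptor known from B cells (4.45 ± 0.42, limma adjusted p = 1.13e-08; edgeR adjusted p = 0.00089) and more Rnd3 (3.87 ± 0.41, limma adjusted p = 6.29e-08; edgeR adjusted p = 0.00124), each in 7 of 7 mice. With edgeR, Lphn3, an adhesion receptor, rose by 4.81 ± 0.65 (adjusted p = 0.000198), Siglec1 by 3.38 ± 0.53 (adjusted p = 0.00089), Spry2 by 3.17 ± 0.54 (adjusted p = 0.00205) and Ppp1r16b by 2.04 ± 0.32 (adjusted p = 0.000893), all in 7 of 7 mice. Arc (limma difference 7.49 ± 0.76) and Dlgap3, a postsynaptic scaffold (2.64 ± 0.36), rose in 7 of 7 mice with edgeR adjusted p of 0.00382 and 0.00291, as did a feature shared by Cyp4a10 and related genes (3.45), whose estimate is uncertain. Limma added Dock3, an activator of the GTPase Rac (4.95 ± 0.49, adjusted p = 1.61e-08), the sorting receptor Sorcs3 (4.43 ± 0.43), Lingo1 (6.81 ± 0.69), the formin Fmnl1 (6.23 ± 0.72), Pde4dip (4.14 ± 0.47) and Bdnf (5.61 ± 0.69, adjusted p = 1.51e-06), each in 7 of 7 mice. Genes that fell included Clasp2, a microtubule plus-end protein (edgeR log2 change -2.46 ± 0.4, adjusted p = 0.00137, 6 of 7 mice). So did, with edgeR, the splicing factor Sfrs2 (-1.68 ± 0.33, adjusted p = 0.00935), the transcription factor Nfia (-2.4 ± 0.5, adjusted p = 0.016) and Pdcd4 (-3.22 ± 0.7, adjusted p = 0.0297), each in 7 of 7 mice. Tmem181b-ps fell as well (edgeR -1.44 ± 0.32, adjusted p = 0.0297, 6 of 7 mice). By limma the clock gene Per3 (-4.9 ± 0.74), Gas7 (-4.39), Ano3 (-3.8), Twf1 (-3.61) and Hmgn3 (-3.55) were lower in 7 of 7 mice, with adjusted p up to 0.000191.

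At 4 h the delayed response list had 30 of 32 members positive (median limma difference 1.81; camera adjusted p = 2.76e-18), with 3 passing in edgeR and 17 in limma (16, and 23 higher with 1 lower, adjusted over the list alone). The rapid response list had 16 of 17 positive (median 0.71; camera adjusted p = 1.47e-07), with 2 passing in edgeR, Gadd45b and Nr4a1, and 5 in limma (7 and 8 adjusted over the list alone), including Gadd45g (4.45 ± 0.76), Atf3 (1.8) and Ier5 (1.62, 6 of 7 mice). Secreted and synaptic plasticity genes had 18 of 25 positive (median 0.54; camera adjusted p = 1.47e-07), with 1 passing in edgeR and 10 higher and 1 lower in limma (10, and 11 with 3, adjusted over the list alone), among them Synpo (5.79 ± 0.76) and Nptx2 (4.25 ± 0.62). The granule cell identity list fell, with 4 of 16 positive (median -1.33; camera adjusted p = 0.00224). In the same nuclei the median share of Malat1 was 14.2% against 8.22% and the median total 489434 against 735546, active against inactive; that share was higher in active nuclei for both ages and times. Of the members of the list 0 passed in edgeR (2 lower adjusted over the list alone). In limma 3 fell, Fam163b (-3.92 ± 0.83), Pitpnc1 (-2.91 ± 0.52) and C1ql3 (-2.74 ± 0.61), while Cdh9 rose (2.23), with 10 lower and 1 higher adjusted over the list alone. MAP kinase feedback (camera adjusted p = 0.0629), mature granule cell (0.0595) and heat shock genes (0.0595) did not pass as groups. With limma means the mature granule list fell (camera adjusted p = 0.0473, adjusted p = 0.179 with an estimated correlation, median -0.87, 4 of 19 positive). Heat shock genes rose with limma means (camera adjusted p = 2.95e-05, median 1.39, 11 of 13 positive). Hsph1 (3.17), Hspa4 (2.71), Dnajb5 (2.88) and Bag3 (1.56, 4 of 7 mice) passed with limma. Dusp4 (1.01) and Spred2 (1.92) rose and Dusp3 fell (-2.46), and of the mature granule list Kcnip3 (2.0) and Pdzd2 (2.35) rose while Rasgrf2 (-2.15) and Ntng1 (-2.46, 5 of 7 mice) fell. In all, edgeR called 38 genes, 32 higher and 6 lower (1333 unadjusted), and limma 661, 360 higher and 301 lower (2449 unadjusted), with 35 called by both. The edgeR count was 85 without the mouse block, 1 without the mice of the smaller 4 h prefix (134, 135 and 138), 22 without mouse 103, 18 without mouse 110 and 23 without mouse 134. Of the 60 genes higher at 1 h by limma, 28 were also higher at 4 h in other mice (1.67 expected of independent lists), as were 5 of the 10 lower ones (0.233 expected).

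**Figure D2:**
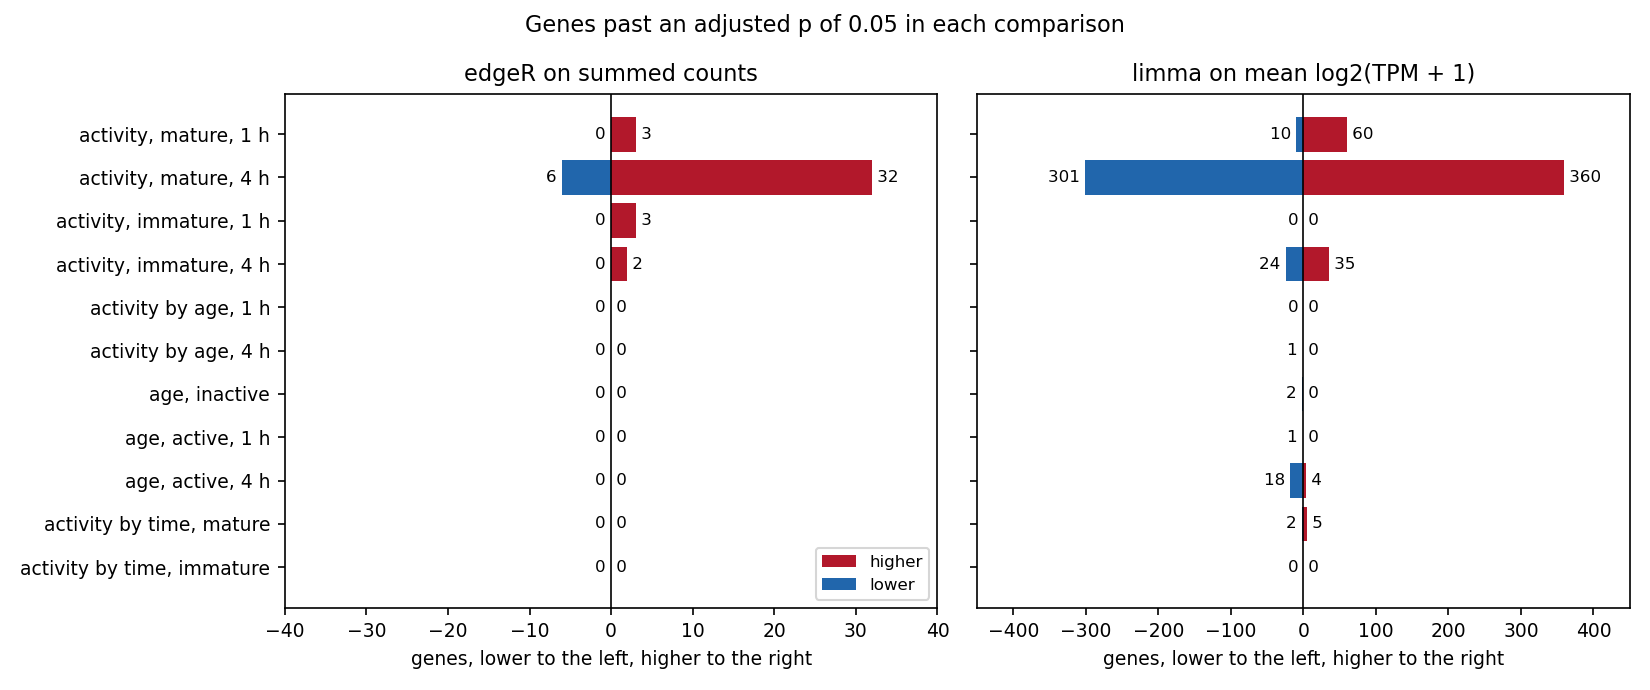
Bars give the number of genes higher or lower at an adjusted p under 0.05 in each comparison, by edgeR on summed counts and by limma on mean log2(TPM + 1), of 12918 genes tested. Limma called 661 genes for activity in mature nuclei at 4 h and edgeR 38.

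The same comparison was made within immature neurons at 1 h. Spry2 rose in active nuclei by 5.12 ± 0.73 (edgeR log2 change ± SE, adjusted p = 0.000732) in 5 of 5 mice, and Abhd2, a lipid hydrolase, by 2.92 ± 0.55 (edgeR adjusted p = 0.0316) in 5 of 5. Inhba rose in 4 of 5 mice (edgeR adjusted p = 0.0267), from 0.29 ± 0.1 (SD, n = 5) to 4.22 ± 3.38 in log2(TPM + 1). With limma these genes were not past the threshold (Spry2 4.24 ± 0.99, adjusted p = 0.292). Its genes with the smallest p, none of which passed, were Sat1 (4.25, limma adjusted p = 0.248, 5 of 5 mice), Atp1b1 (2.84, 0.248, 5 of 5) and Plk2 (4.76, 0.292, 4 of 5). The rapid response list rose with 17 of 17 members positive (median limma difference 0.85; camera adjusted p = 4.32e-11), with 0 members passing in either tool (9 in edgeR and 0 in limma adjusted over the list alone). The delayed response list had 28 of 32 positive (median 0.67; camera adjusted p = 4.74e-12), 2 passing in edgeR and 0 in limma (6 and 4 adjusted over the list alone). Secreted and synaptic plasticity genes had 15 of 25 positive (median 0.28; camera adjusted p = 0.00142, and adjusted p = 0.0544 with an estimated correlation; 6 in edgeR and 3 in limma adjusted over the list alone). MAP kinase feedback genes had 8 of 14 positive (median 0.19; camera adjusted p = 0.0268, adjusted p = 0.155 with an estimated correlation and 0.104 without the mouse block; 1 in each tool adjusted over the list alone). EdgeR called 3 genes, all higher (839 unadjusted), and 0 without the mouse block. Limma called 0 (433 unadjusted), and 5 without mouse 70. Inhba and Abhd2 were lost when any of the mice 60, 62, 66 or 69 was left out, which left 1 call each time.

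In immature neurons at 4 h, Inhba rose in 5 of 5 mice (limma difference 4.69 ± 1.01, adjusted p = 0.0246; edgeR adjusted p = 0.00194). Malat1 rose by 1.01 ± 0.18 with edgeR (adjusted p = 0.0191) in 5 of 5 mice by summed counts, but did not pass with limma (0.74 ± 0.23, adjusted p = 0.158). Neat1, the RNA scaffold of paraspeckles, passed with limma (2.59 ± 0.62, adjusted p = 0.0486) and not with edgeR (adjusted p = 0.0703), and Lphn3 (3.21 ± 0.65) and Spry2 (2.98 ± 0.62) were at the same edgeR adjusted p. With limma, Ptprz1, a receptor tyrosine phosphatase (3.08 ± 0.52), Lingo1 (4.34 ± 0.8), Plekha2 (3.21 ± 0.57) and the ephrin receptor Epha10 (3.99 ± 0.73) rose in 5 of 5 mice with an adjusted p of 0.00805. Jun, a subunit of AP-1, rose by 3.24 ± 0.61 in 5 of 5 mice (limma adjusted p = 0.00864). Dbc1 (4.65), Ankrd33b (4.27) and Itga11 (2.19) were higher in 5 of 5 mice and Ppme1 (3.19) and Arc (4.17 ± 0.88) in 4 of 5, with limma adjusted p up to 0.0209. Tia1, an RNA-binding protein of stress granules, fell by 4.41 ± 0.77 and Pdcd4 by 3.73 ± 0.67 (limma adjusted p = 0.00805 each, 5 of 5 mice). Dpf1 (-3.25), Pitpnc1 (-2.91), Csad (-2.44), Fmo1 (-2.39), Tmem181b-ps (-2.23), Mndal (-1.27) and Kif26b (-1.09) were also lower in 5 of 5 mice by limma, as was the feature shared by Tubb2a-ps2 and Tubb2b (-1.84), with adjusted p up to 0.0327.

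The delayed response list rose in immature nuclei at 4 h with 30 of 32 members positive (median limma difference 1.43; camera adjusted p = 4.22e-19), with 1 passing in edgeR and 3 in limma, Inhba, Mapk4 (2.79) and Vgf (2.56, 4 of 5 mice). Adjusted over the list alone these counts were 10 and 14. The rapid response list had 13 of 17 positive (median 0.66; camera adjusted p = 0.00112, adjusted p = 0.163 with an estimated correlation), with Gadd45b (1.99, 4 of 5 mice) passing in limma (3 in each tool adjusted over the list alone). Secreted and synaptic plasticity genes had 15 of 25 positive (median 0.53; camera adjusted p = 0.00224, adjusted p = 0.0599 with an estimated correlation; 3 in edgeR, and 6 higher with 1 lower in limma, adjusted over the list alone). MAP kinase feedback genes had 9 of 14 positive (median 0.18; camera adjusted p = 0.0285, adjusted p = 0.156 with an estimated correlation and 0.0659 without the mouse block; 3 in edgeR and 2 in limma adjusted over the list alone). Oligodendrocyte lineage markers were higher in the same nuclei, with 7 of 7 positive (median 0.79; camera adjusted p = 0.0162, adjusted p = 0.262 with an estimated correlation) and 0 members passing in either tool, alone or over all genes. Mbp, a myelin protein gene, had a count in 62.5% of the 32 immature active nuclei and in 41% of the 61 inactive ones. EdgeR called 2 genes, both higher (1071 unadjusted), and 31 without the mouse block. Limma called 59, 35 higher and 24 lower (1520 unadjusted), and 20 without the block, with 1 gene called by both tools. The limma count was 21 without mouse 106, 2 without mouse 110, 93 without mouse 134 and 36 without mouse 138, and the edgeR count was 1 without mouse 106, 113 or 138. Of the genes changed in mature nuclei at 4 h by limma, 22 were also higher (0.975 expected of independent lists) and 10 also lower (0.559 expected) in immature ones, in other nuclei of overlapping mice.

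The title of the series asks whether activity evokes a smaller response in immature than in mature neurons, and the test of that difference called few genes. In simulated nuclei, drawn without differences between mice, this test recovered few changed genes. For 64-fold changes the shares were 10% at 1 h and 23.3% at 4 h with limma, and 11.7% and 13.3% with edgeR. Few calls therefore say little. At 4 h the activity change of Dock3 was lower in immature nuclei by limma (-4.81 ± 0.76, adjusted p = 0.00323). Dock3 lay at 6.13 ± 1.55 (SD, n = 8) in mature active and 1.49 ± 1.46 in mature inactive nuclei. It lay at 2.35 ± 1.89 (n = 5) and 1.8 ± 0.88 (n = 8) in immature ones. Without the mouse block this call was lost (limma adjusted p = 0.136). No other gene passed; those with the next smallest limma p at 4 h were Gas7 (4.6, adjusted p = 0.103) and Acat1 (-3.09, 0.103), and with edgeR Npy, Stox2 and Gmeb1 (adjusted p = 0.59). At 1 h edgeR and limma each called 0 genes (671 and 318 unadjusted). The smallest p there were those of Mtch1, Six4 and Il1f9 with edgeR (adjusted p = 0.888) and of Midn, Rgs7bp and Shisa7 with limma (adjusted p = 1). At 4 h edgeR called 0 (821 unadjusted) and limma 1 (1203 unadjusted). The limma count was 8 without mouse 110, 7 without mouse 121, 6 without mouse 113, 4 without mouse 106 and 2 without mouse 134, 135 or 138. The delayed response list had a smaller activity change in immature nuclei at 1 h, with 3 of 32 members positive (median -0.74; camera adjusted p = 0.0439, adjusted p = 0.407 with an estimated correlation), but not at 4 h (camera adjusted p = 0.979). With limma means it was smaller at both times (camera adjusted p = 2.88e-10 at 1 h; 0.00065 at 4 h, with adjusted p = 0.23 with an estimated correlation). Its members passing were 0 in edgeR and in limma at 1 h, also adjusted over the list alone.

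The score of each list per nucleus, averaged per mouse, gave the size of the response. At 1 h the delayed response score, in mean log2(CPM + 1), was 3.64 in mature active and 1.14 in mature inactive nuclei. The difference was 2.5 ± 0.64 (SD, n = 5 mice, higher in 5 of 5; exact sign-flip permutation p = 0.063, and 0.00794 in an exact test without pairing by mouse). In immature nuclei the difference was 1.26 ± 1.12 (n = 5, higher in 4 of 5; exact p = 0.125, and 0.0397 without pairing), and the immature minus the mature change was -1.24 ± 0.92 (n = 5, higher in 0 of 5; exact p = 0.063). At 4 h the mature difference was 2.78 ± 0.75 (n = 7, higher in 7 of 7; exact p = 0.0156). The immature one was 1.77 ± 0.79 (n = 5, higher in 5 of 5; exact p = 0.063, and 0.000777 without pairing). Their difference was -1.15 ± 0.55 (n = 4, higher in 0 of 4; exact p = 0.125). The rapid response score differed by 1.82 ± 0.73 in mature nuclei (n = 5, 5 of 5; exact p = 0.063, and 0.0159 without pairing). It differed by 0.95 ± 0.88 in immature ones (n = 5, 4 of 5; exact p = 0.125) at 1 h. Their difference was -0.87 ± 1.14 (n = 5, higher in 0 of 5; exact p = 0.063), and -0.4 ± 0.54 without mouse 70 (n = 4, exact p = 0.125). These values were 1.22 ± 0.66 (n = 7, 7 of 7; exact p = 0.0156), 0.66 ± 0.61 (n = 5, 5 of 5; exact p = 0.063, and 0.0163 without pairing) and -0.75 ± 0.4 (n = 4, higher in 0 of 4; exact p = 0.125) at 4 h. The two-sided test can give no p below 0.063 with 5 mice, 0.125 with 4 and 0.0156 with 7, so the difference between ages could not pass the threshold at either time with these mice. With every mouse that had a nucleus in each state at 4 h (n = 8) it passed, at -1.02 for the delayed (exact p = 0.00781) and -0.55 for the rapid response score (exact p = 0.0391). Without the smaller 4 h prefix the mature changes at 4 h had an exact p of 0.063 each.

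**Figure D3:**
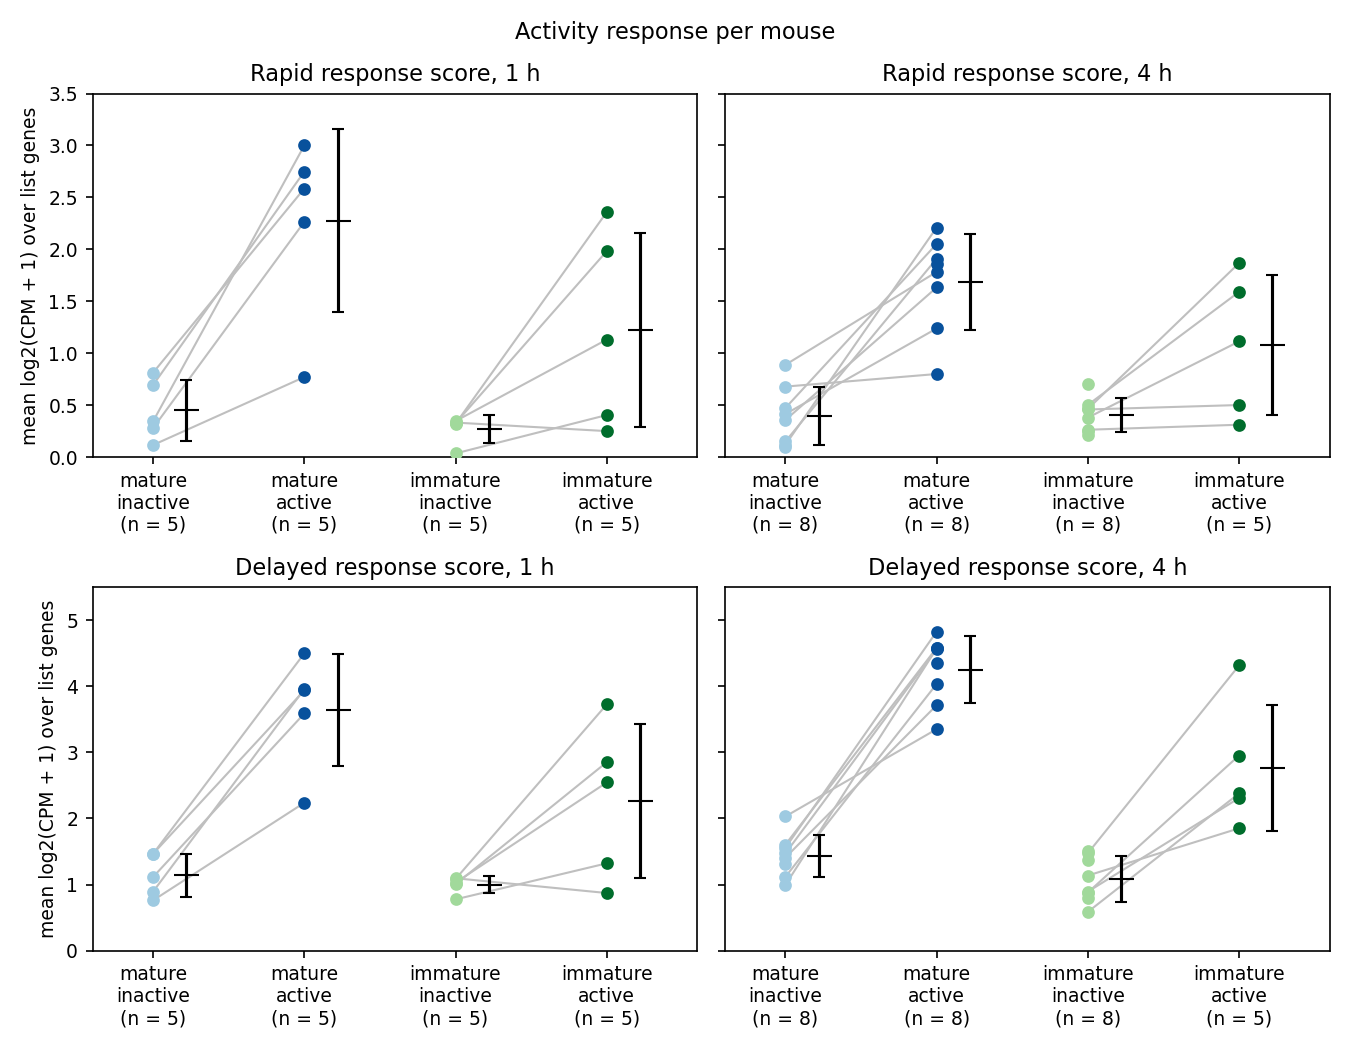
Points give the rapid and delayed response scores (mean log2(CPM + 1) over 17 and 32 genes) of each mouse by state at 1 h and 4 h, lines join the states of 1 mouse, and bars give the mean ± SD over mice (n = 5 per state at 1 h; at 4 h 5 for immature active nuclei and 8 for the others). The mean delayed response score at 1 h lay at 3.64 in mature active and 2.26 in immature active nuclei.

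The response was also measured on genes chosen for a rise in mature nuclei of other mice. Genes that rise in immature nuclei alone are not among them, so this choice favours the mature response. For genes picked by edgeR without the mouse measured, the log2 change at 1 h was 5.51 ± 1.61 (SD, n = 5) in mature and 4.76 ± 2.41 in immature nuclei of that mouse. The difference was -0.75 ± 2.36 (higher in 1 of 5; exact sign-flip permutation p = 0.562) over 2 to 4 genes. With 1 mouse left out it ranged from -1.43 without mouse 62 to 0.19 without mouse 70. The change at 4 h was 4.76 ± 0.57 in mature and 3.25 ± 0.91 in immature nuclei, a difference of -1.5 ± 0.81 (n = 4, higher in 0 of 4, exact p = 0.125) over 16 to 24 genes. On the rapid and delayed response lists the difference was -1.25 and -2.39 at 1 h (exact p = 0.5 and 0.188). At 4 h it was -1.71 and -0.85 (exact p = 0.125 each). With genes picked by limma, a choice made after seeing the data, the difference was -1.34 ± 1 at 1 h (n = 5, higher in 0 of 5, exact p = 0.063, 15 to 52 genes). At 4 h it was -0.93 ± 0.71 (n = 4, higher in 1 of 4, exact p = 0.25, 293 to 338 genes). On summed counts of these genes it was -1.33 at 1 h (higher in 2 of 5, exact p = 0.25). The value at 4 h was -1.54 (higher in 0 of 4, exact p = 0.125). The median edgeR difference of all tested genes between ages was -0.37 at 1 h and -0.28 at 4 h, in the same direction. Numbers of genes called can depend on numbers of nuclei, so equal numbers were drawn in both ages. In the limma fit used for these draws, all nuclei of the 5 mice at 1 h gave 26 genes in mature and 0 in immature nuclei. With 82 nuclei of these mice drawn 20 times, limma called a median of 8.5 genes in mature nuclei (range 0 to 19) and 0 in immature ones. The medians at an unadjusted p under 0.05 were 1288.5 and 670 genes. At 4 h all nuclei of 4 mice gave 1 gene in mature and 0 in immature nuclei. With 36 nuclei of these mice the median was 0 in both ages, with 920.5 and 643 genes unadjusted. A fall from 1 gene to 0 says little about the number of nuclei. The immature medians of 670 and 643 lie near the share of 0.05 of 12918 genes that chance alone would give. The mature medians lie above it. Genes detected per nucleus, thinned to 93752 counts, did not pass the threshold in any comparison. With 5 mice or fewer, as in all comparisons at 1 h, the exact test could not have passed it. Immature active nuclei at 1 h had -223 ± 1.9e2 (SD) genes relative to inactive ones (n = 5, higher in 0 of 5; exact p = 0.063), and -1.4e2 without mouse 60. They had -215 ± 264 (SD) relative to mature active ones (n = 5, higher in 0 of 5; exact p = 0.063), and -1.0e2 without mouse 60. The other exact p were 0.375 or more.

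Age was compared in nuclei of like activity. In inactive nuclei of both times, immature neurons held less Snhg11, a small nucleolar RNA host gene (limma difference -3.28 ± 0.48, adjusted p = 0.000867, 12 of 12 mice). They held less Ntng1, the adhesion protein netrin-G1 (limma -3.21 ± 0.56, adjusted p = 0.0089, 12 of 12). Snhg11 lay at 3.78 ± 1.12 (SD, n = 5) in immature and 6.9 ± 1.7 in mature inactive nuclei at 1 h, and at 4.38 ± 1.39 and 7.96 ± 1.16 (n = 8) at 4 h. Genes of the immature neuron list were higher in immature nuclei, with 18 of 20 positive (median limma difference 0.5; camera adjusted p = 3.71e-06), although 0 members passed over all genes (3 in edgeR and 4 in limma adjusted over the list alone). Dcx, doublecortin, was at 0.91 ± 0.7 against 0.33 ± 0.53 at 1 h. The mature granule cell list did not pass as a group (camera adjusted p = 0.575), with Ntng1 its only member past the threshold. Its mean level over nuclei and 19 genes was 1.18 in immature against 1.52 in mature inactive nuclei at 1 h. At 4 h it was 1.44 against 2.06 in log2(TPM + 1). EdgeR called 0 genes (812 unadjusted), and 4 without the mouse block, and limma called 2, both lower (937 unadjusted). The limma count was 4 without mouse 70 or 113 and 1 without mouse 60, 66 or 69, when Ntng1 was lost. Genes next in limma were Il1f9 (-1.25, adjusted p = 0.0939, 10 of 12 mice) and Shisa4 (-2.18, 0.0939, 12 of 12), and in edgeR Slc6a15, Cox11 and Snhg11 (adjusted p = 0.34).

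Among active nuclei at 1 h, Midn, a nuclear protein gene induced by activity in the mature comparison above, was lower in immature than in mature nuclei (limma difference -2.14 ± 0.34, adjusted p = 0.00313, 5 of 5 mice). It lay at 0.41 ± 0.49 against 2.55 ± 0.44 (SD, n = 5). Delayed response genes were lower with 3 of 32 positive (median -0.87; camera adjusted p = 1.73e-07; 4 in edgeR and 12 in limma adjusted over the list alone, 0 over all genes). The rapid response list was lower with 2 of 17 positive (median -0.97; camera adjusted p = 0.01, adjusted p = 0.299 with an estimated correlation; 0 in edgeR and 7 in limma adjusted over the list alone). Nr4a3 (-1.51), Tsc22d2 (-2.07) and Rnf217 (-1.17) did not pass (limma adjusted p = 0.16, 5 of 5 mice each), nor did Rnd3, Dhx40 and Ptgs2 in edgeR (adjusted p = 0.813). EdgeR called 0 genes (629 unadjusted) and limma 1 (444 unadjusted). The limma count was 0 without mouse 60, 62 or 69 and 3 without mouse 66. Among active nuclei at 4 h, Dock3 (-4.51 ± 0.58, adjusted p = 4.42e-05), Rnd3 (-3.09 ± 0.49, adjusted p = 0.00177) and Blnk (-2.73 ± 0.5, adjusted p = 0.0106) were lower in immature nuclei by limma in 4 of 4 mice. So were Pde4dip (-3.26), Npy, neuropeptide Y (-3.48 ± 0.71), Pde8b (-2.99), Pttg1ip (-2.31), the kinesin Kif17 (-2.13), Megf11 (-2.13) and Gpr158 (-1.74), with adjusted p up to 0.0356, while Ptgs2, cyclooxygenase 2 (-3.16), and Sorcs3 (-2.67) were lower in 3 of 4. Kifap3 (2.98 ± 0.67) and Nfia (2.45 ± 0.55) were higher in 4 of 4 mice (limma adjusted p = 0.0469 each). Delayed response genes did not pass on summed counts (camera adjusted p = 0.15) and passed with limma means (camera adjusted p = 3.03e-09, median -0.97), with 3 members lower in limma (14 adjusted over the list alone). EdgeR called 0 genes (805 unadjusted), and 1 without the mouse block, with Nfia, Sorcs1 and Clasp2 at its smallest p (adjusted p = 0.591). Limma called 22, 4 higher and 18 lower (1240 unadjusted). It called 13 without mouse 103, 54 without mouse 110, 7 without mouse 113, 41 without mouse 121 and 14 without mouse 134.

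The activity change of a few genes differed between 1 h and 4 h in mature nuclei by limma. Dock3 (5.31 ± 0.77, adjusted p = 0.000606) and Blnk (3.93 ± 0.66, adjusted p = 0.00476) had a larger change at 4 h. So had Sorcs3 (limma 3.98 ± 0.68, adjusted p = 0.00476), the cadherin Cdh2 (3.21 ± 0.6, adjusted p = 0.0161) and Megf11 (2.87 ± 0.57, adjusted p = 0.0327). Kdm6b (-5.4 ± 1.02, adjusted p = 0.0161) and Bc049807 (-3.88 ± 0.8, adjusted p = 0.0412) had a larger change at 1 h. Kdm6b lay at 8.08 ± 1.4 (SD, n = 5) in active and 3.15 ± 0.61 in inactive nuclei at 1 h and at 3.95 ± 0.74 and 4.47 ± 0.72 (n = 8) at 4 h. Blnk lay at 0.94 and 0.41 at 1 h and 5.15 ± 1.74 and 0.58 ± 0.37 at 4 h. EdgeR called 0 genes (697 unadjusted; Snx25, Kdm6b and Car5a at adjusted p = 0.771) and limma 7 (835 unadjusted), with 1 without mouse 60 or 69, 4 without mouse 66, 12 without mouse 113 and 18 without mouse 121. In immature nuclei edgeR and limma each called 0 genes (728 and 589 unadjusted). The smallest p were those of Entpd7, Kif26b and Mndal (edgeR adjusted p = 0.702) and of Kdm6b (-4.93), Ptprz1 (3.34) and Pfas (4.29; limma adjusted p = 0.403). Mice of the 2 times also differ in library batch, so these differences cannot be told apart from batch. The balance of the sexes differed too. At 1 h mice 60, 62 and 66 were female and mice 69 and 70 male, while at 4 h only mice 121 and 138 were female.

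Lists of other functions and cell types did not pass the threshold on summed counts in any of the 11 comparisons. Their lowest camera adjusted p were 0.0595 for the mature granule cell list and 0.115 for neural stem and progenitor genes (both for activity in mature nuclei at 4 h; 0.0473 and 0.0113 with limma means). They were 0.241 for GABAergic interneuron (activity, immature, 1 h) and for microglia (age, active, 4 h). They were 0.365 for CA pyramidal and mossy cell genes (difference of the activity change between ages, 4 h) and for GABA receptors (difference between times, mature). Those left were 0.437 for axon guidance (activity, immature, 4 h), 0.452 for potassium channels, 0.639 for astrocytes and 0.663 for glutamate receptors (activity, immature, 1 h). In that comparison the astrocyte list had a positive median (0.06) and test but a negative mean (-0.19), and the potassium channel list a positive test and limma median (0.01) but a negative edgeR median (-0.24). For activity in mature nuclei at 4 h the potassium channel test was positive with a limma median of -0.12 and mean of 0.44, and the glutamate receptor test negative with a median of -0.06 and mean of 0.07. Of the 23 list calls, 14 held with an estimated correlation. Members of these lists that passed for activity in mature nuclei at 4 h by limma were Nrp1 (5.01 ± 0.67, 6 of 7 mice), Epha7 (1.92, 5 of 7; also in edgeR, adjusted p = 0.0148), Sema6d (1.63, 7 of 7) and Sema5a (-2.26, 6 of 7) of axon guidance. Sox9 of the neural stem list passed as well (0.64, 6 of 7). The genome positions (GRCm38) of genes named here are chromosome 13, 16011851 to 16031621, plus strand, for Inhba; chromosome 14, 105891947 to 105896819, minus strand, for Spry2; chromosome 19, 53892231 to 53929860, plus strand, for Pdcd4; and chromosome 9, 106892825 to 107231909, minus strand, for Dock3. All 4 are annotated as protein coding.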

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

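Of the tests in this part, only the 2 on thinning to a common depth were set before their own results were seen, though not before the data were; the others, the splits of the samples included, were chosen after.

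Of 80200 pairs of nuclei, 4 had closely matching counts (correlations 0.952, 0.925, 0.748 and 0.739, against a median of 0.272), and 1 of them joins a male and a female mouse. Chance likeness of nuclei of 1 cell type is argued against, since the lowest of the 4 was 0.739 and the next pairs lay at 0.613 and 0.611. The Xist level of 795 CPM in the nucleus labelled male, where the next male nucleus had 19.7 CPM, is consistent with RNA of 1 nucleus in both libraries or 1 library under 2 labels. The chi-square per degree of freedom of the closest pair was 1.28, over the 99% limit of 1.07 for counting noise and under the lowest of 300 other pairs (8.97), and since the counts are estimates, 1 library sequenced 2 times stays open. Which of the 2 labels of that pair is right stays open, and no biological explanation was tested.

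Limma called fewer genes for activity in immature than in mature nuclei, edgeR did so at 4 h (2 against 38) but not at 1 h (3 and 3), and the mean change of both scores was lower in them, while the test of that difference called few genes and recovered few in simulated nuclei (limma 10% and 23.3% of 64-fold changes at 1 h and 4 h); a biological difference with age stays open. At 4 h the mature comparison in the 4 mice with both ages called 1 gene by limma with all nuclei and a median of 0 at matched numbers, so the count of calls decides nothing about fewer nuclei and mice, and genes at an unadjusted p under 0.05 were 836 to 1000 in mature and 584 to 696 in immature draws. At 1 h both ages had the same number of nuclei of 5 mice. In the fit used for the draws, limma called 26 genes in mature and 0 in immature nuclei with all of them. With 82 drawn it called a median of 8.5 genes (range 0 to 19) in mature nuclei and 0 in every immature draw. Genes at an unadjusted p under 0.05 were 1153 to 1396 in mature and 596 to 743 in immature draws. The immature ranges at both times include the number that chance alone would give, a share of 0.05 of 12918 genes. Different depth is argued against at 4 h, where the difference of the delayed response in thinned nuclei was -1.27 (n = 4 mice, higher in 0 of 4). At 1 h that difference was -0.69 without mouse 70, which kept too few mature inactive nuclei (n = 4, higher in 1 of 4), against -0.87 unthinned in the same 4 mice, which leaves depth open. Arc itself had a lower mean level in immature than in mature active nuclei at both times. In mouse 70, immature active nuclei scored below inactive ones (delayed 0.87 against 1.1, rapid 0.25 against 0.33). Whether the nuclei sorted as active were equally active in both ages was not tested.

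The activity change of 7 genes in mature nuclei differed between 1 h and 4 h by a test of the difference in limma: Dock3 (5.31), Blnk (3.93), Sorcs3 (3.98), Cdh2 (3.21), Megf11 (2.87), Kdm6b (-5.4) and Bc049807 (-3.88). Different numbers of genes detected at the 2 times stay open. With genes detected as a covariate 7 of 7 genes kept their call. Each mouse was of 1 time, so the mouse block already held that difference, and the covariate adjusted only within mice. Library batch stays open, since 0 library name prefixes hold mice of both times, and a biological difference between times stays open with it. The balance of the sexes also differed between the times and was not tested.

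By the same kind of test, the activity change of Dock3 was lower in immature than in mature nuclei at 4 h (limma difference -4.81). The delayed response list differed in the same way at 1 h (camera adjusted p = 0.0439, and adjusted p = 0.407 with an estimated correlation). Of 88 groups of values looked through, 3 held a mouse standing apart from the others, and chance marks about 1 in 20 groups. The activity change of Twf1 in mature nuclei at 4 h was -7.17 in mouse 113 and -3.9 to -1.89 in the other mice (n = 7). In immature nuclei at 4 h (n = 5) that of Epha10 was 8.31 in mouse 110 and 2.35 to 3.44 in the others, and that of Pitpnc1 was -1.26 in mouse 110 and -3.64 to -3.28 in the others.

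Other splits of the samples were put through the same tests. With limma, 2 of 100 splits, the real one included, reached the 2 genes for age in inactive nuclei. The highest other was 2, so another split gave as many. For the difference between times in mature nuclei 1 of 100, the real one, reached the 7 genes (highest other 5). Few splits reached these counts, which argues against chance but does not exclude it, since many comparisons were split after the counts were seen. For activity the counts were reached in 1 of 100 splits in mature nuclei at 1 h (70 genes, highest other 4) and at 4 h (661, highest other 150) and in immature nuclei at 4 h (59, highest other 25), but few of these splits part the states within as many mice as the real labels (14, 7 and 2 of the 100, the real one included, with highest others of 2, 91 and 2). For age in active nuclei at 4 h (22) 3 of 100 splits reached as many, with a highest other of 77, which points to a structure of the samples that was not tested further. The splits for activity and for age in active nuclei need not keep the values of a mouse paired; the exchanges within mice below do. Chance cannot be excluded with limma for the difference between ages at 4 h (1, 41 of 100, highest other 29) and age in active nuclei at 1 h (1, 9 of 100, highest other 2). A count of 0 is reached by every split and tests nothing, as for activity in immature nuclei at 1 h (100 of 100, highest other 2) and the difference between times in immature nuclei (100 of 100, highest other 4). For the difference between ages at 1 h the 16 splits are too few (0, highest other 0). With edgeR on only the groups compared, activity in mature nuclei at 1 h (3 genes, 1 of 40, highest other 0) and 4 h (12, 1 of 22, highest other 0) has only 4 splits and 1 split, the real one included, that part as many mice, which are too few. Its 0 genes for activity in immature nuclei (40 of 40 splits at 1 h, 22 of 22 at 4 h, highest other 0) test nothing either, and the 3 and 2 genes called with all groups were not put through splits. For the remaining edgeR comparisons the 5 or 10 splits are too few (0 genes, highest other 0). With states exchanged within mice, only the real labels reached the count for activity in mature nuclei at 4 h (661, 1 of 64, highest other 422). This argues against chance but does not exclude it. Another exchange gave 422 genes, and the test was chosen after the counts were seen. The exchanges are too few for activity in mature nuclei at 1 h (70, 1 of 16, highest other 2), in immature nuclei at 1 h (0, 16 of 16, highest other 2) and 4 h (59, 1 of 16, highest other 8), and for age in active nuclei at 1 h (1, 2 of 16, highest other 2) and 4 h (22, 2 of 8, highest other 54).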

How the results depend on the processing

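Every alternative for the limma counts, and the settings on near-identical pairs, weights, log2(TPM + 10), covariates, the scores without a prefix or thinned, held-out genes chosen by limma and the lists on limma means, were chosen after seeing the data; limma in place of edgeR for gene counts and the other alternatives for edgeR, scores and lists were planned. No result past its threshold changed sign. Of the edgeR counts, 90 stayed within 1.5 times of the reported count and 38 moved under other settings, and 88 stayed and 10 moved with 1 mouse left out; of the limma counts these numbers were 67, 39, 62 and 36. Called lists kept it 81 times and lost it 11 times. Depth limits what can be called in a nucleus, and the mice limit the p-values. The cause of the changes below was not tested, except that fewer mice or nuclei go into some settings by construction.

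DESeq2 called 1417, 2222, 1046 and 1689 genes for activity (mature 1 h and 4 h, immature 1 h and 4 h). It called 973 and 1341 for the difference between ages at 1 h and 4 h. For age it called 1126, 913 and 1341 (inactive, active 1 h, active 4 h), and for the difference between times 1157 and 1178 (mature, immature). In the simulation, where its size factors were estimated in another way, it also called unchanged genes. Limma in place of edgeR called 70, 661, 0 and 59 genes for activity, 1 for the difference between ages at 4 h, 2, 1 and 22 for age and 7 for the difference between times in mature nuclei, and 40 lists against 23. An estimated correlation left 14 lists. Without the mouse block edgeR called 1, 85, 0 and 31 genes for activity and 4 and 1 for age (inactive, active 4 h), and limma 44 (mature 1 h), 20 (immature 4 h) and 0 (difference between ages, 4 h); it moved no other count over 1.5 times, ended the calls of 2 lists and of genes named in the report, and changed those of scores. Scores without pairing, by exact permutation tests, were 1.82 (rapid, mature 1 h, p = 0.0159, n = 5), 0.67 (rapid, immature 4 h, p = 0.0163), 2.5 (delayed, mature 1 h, p = 0.00794), 1.26 (delayed, immature 1 h, p = 0.0397) and 1.68 (delayed, immature 4 h, p = 0.000777).

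For activity in mature nuclei at 4 h edgeR called 5 genes with sums of at least 5 nuclei, 12 with only the groups compared and 1 without prefix X121119. For activity in immature nuclei at 4 h it called 0 in each of these 3 settings, 11 with a count in at least 80 nuclei, 12 with sums of at least 1 nucleus, 5 without nuclei with few genes and 1 without the near-identical pairs. For activity in immature nuclei at 1 h it called 0 with only the groups compared and 1 with no filter. With sums of at least 5 nuclei limma called 1 and 0 (activity, immature 1 h and 4 h), 1 (difference between ages, 1 h), 3 (age, active 1 h) and 22 (difference between times, mature); with at least 1 nucleus 46 (activity, mature 1 h), 160 (immature 4 h), 2 (difference between ages, 4 h) and 44 (age, active 4 h). Without prefix X121119 limma called 1.9e2 (activity, immature 4 h), 3 (difference between ages, 4 h), 34 (age, active 4 h) and 2 (difference between times, immature). With a count in at least 80 nuclei it called 4, 0 and 16 (age, inactive; age, active 1 h; difference between times, mature), and without nuclei with few genes 2 and 35 (difference between ages, 4 h; age, active 4 h). Without the near-identical pairs it called 37, 6 and 2 (activity, immature 4 h; difference between ages, 4 h; age, active 1 h). Weighted by nuclei it called 242, 5 and 0 (activity, mature 1 h, immature 1 h and 4 h), 1 (difference between ages, 1 h), 13, 20 and 10 (age) and 31 (difference between times, mature). On log2(TPM + 10) it called 1 and 39 (activity, immature 1 h and 4 h), 2 (difference between ages, 4 h), 4 and 5 (age, inactive and active 1 h), and with genes detected as a covariate 39 (activity, immature 4 h) and 1 (age, inactive).

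At 4 h the mature scores were 1.52 and 2.85 (rapid, delayed) without prefix X121119 (exact p = 0.063 each, n = 5) and 1.23 and 3.05 with mice of at least 5 nuclei in each state (exact p = 0.25 each, n = 3). With mice of at least 1 nucleus in each state (n = 8) the immature scores at 4 h were 0.65 and 1.73 (exact p = 0.00781 each), and the differences between ages -0.55 (exact p = 0.0391) and -1.02 (exact p = 0.00781). Genes detected went from -72.2 to 24.3 (immature minus mature, inactive, 1 h) and from 65.3 to -11.3 (activity, mature 4 h) when a gene needs 5 counts, and without thinning to -327 (activity, mature 4 h) and from -386 to 94 (immature minus mature, active, 4 h).

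With 1 mouse left out, edgeR called 18 to 44, 1 to 2 and 1 to 3 genes for activity (mature 4 h, immature 1 h and 4 h). Limma called 19 to 58, 0 to 5 and 2 to 93 for activity (mature 1 h, immature 1 h and 4 h), 1 to 8 for the difference between ages at 4 h, 1 to 4, 0 to 3 and 7 to 54 for age (inactive, active 1 h, active 4 h), and 1 to 18 and 0 to 1 for the difference between times (mature, immature). Genes detected ranged from -138 to 0.693 (activity, mature 1 h), -166 to 36.5 (immature minus mature, inactive, 1 h) and -40.2 to 1.6e2 (activity, mature 4 h), and the held-out difference at 1 h from -1.43 to 0.19.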

Other observations

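The choice of values in this part was made after the data were seen, and no tests were added for it. In mature active nuclei at 4 h, ion channel and receptor genes were among those past the threshold by limma although their lists were not: 6 of 25 potassium channel, 1 of 19 glutamate receptor and 2 of 13 GABA receptor genes passed, all higher, while 12, 6 and 8 members were positive. Of all 12918 genes tested limma called 661 in this comparison, 360 of them higher, so 1 of 19 is near the share of all genes. The potassium channel genes Kcnk1 (4.45 ± 0.84, SE; adjusted p = 0.000806, 6 of 7 mice), Kcna1 (3.21 ± 0.72, adjusted p = 0.00517, 7 of 7), Kcna4 (2.31 ± 0.53, adjusted p = 0.00623, 6 of 7) and Kcnj4 (1.83 ± 0.43, adjusted p = 0.00798, 7 of 7) rose, in limma. The NMDA receptor subunit Grin2a (3.74 ± 0.96, adjusted p = 0.0154, 7 of 7) and the GABA receptor subunits Gabrb2 (2.67 ± 0.51, adjusted p = 0.000871, 6 of 7) and Gabra4 (2.64 ± 0.72, adjusted p = 0.0236, 6 of 7) also rose, in limma.

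Mbp was at 1.73 ± 1.24 log2(TPM + 1) (SD, n = 5 mice) in immature active and 0.58 ± 0.64 in immature inactive nuclei at 1 h, and at 2.1 ± 0.79 and 1.2 ± 0.51 in mature active and inactive ones. The 15 genes of the oligodendrocyte lineage list did not follow as a whole at 1 h. Their mean level over nuclei was 0.4 against 0.39 in immature and 0.54 against 0.52 in mature nuclei, active against inactive.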
